A study of Oryza sativa Japonica Group with 17 samples.

How the data were processed

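The series covers 17 samples of 12-day-old seedling leaves: 5 bisulfite, 8 RNA-seq, 2 small RNA and 2 chromatin immunoprecipitation libraries. Samples were grouped by their titles. FastQC, Trimmomatic, TopHat, HTSeq, DESeq2, Bowtie, Bowtie2 (2.1.0) and edgeR are named in the submitters' processing notes without roles, and the genome build was not given in the sources used here.

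For RNA-seq, the authors deposited a table of their own comparison without a header line. Its columns were identified from the values and follow the order in which DESeq2 writes its results. The authors made the signal in the table as the mean over the 4 libraries of counts normalized by dividing them by size factors. The authors' log2 values are fold changes between the genotypes from the DESeq2 model, moderated towards 0 at low counts. A standard error, a Wald score, a p-value and an adjusted p-value follow in the deposited table. The deposited score equalled fold over standard error within 1.66e-06, and the deposited adjusted p-value equalled a Benjamini-Hochberg adjustment within 2.46e-07. The table held 55986 loci, of which 14584 had a mean count of 0 and 29212, with a mean of at least 2.88, had an adjusted p. The authors' table has no value per library, so nothing was refitted and the total reads per library are unknown. Size factors recovered from the lowest mean counts were 0.891 and 1.10 in the wild type and 0.888 and 1.15 in the mutant. The design fixed beforehand provided for reading the authors' deposited values at 0.05 in that case. The sign was turned so that values are mutant over wild type.

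For histone marks, the authors called peaks with MACS 1.4.2 per the file headers, on 1 library per mark, with a p-value limit of 1e-05 and no control. Read counts per peak, the peak score (from the p-value) and the fold enrichment (a ratio to local background) are the authors' values per the file headers. Header texts and labels give ZH11 for H3K9me2, whereas the series' file list names Cr-DJ; the labels were followed. The small RNA files list 1 alignment per line; a count of identical lines in the deposited files gave the reads per position. All lines are on the plus strand, 99.4% (Cr-DJ) and 99.1% (osdrm2) are 24 nt long, and no listed position has fewer than 4 reads. How reads with several positions were treated is not given in the sources used here.

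15 gene lists with 152 pairs of locus and name were fixed before the data were examined. The reference table used for names (assembly ASM3414082v1) holds no such locus identifiers, so a pair was accepted when its name, or an alias written after the table was seen, stood on the same chromosome and in the order of the locus numbers. This held for 93 pairs, and only those names are printed, with OsDDM1a, OsDDM1b and OsFIE1 as exceptions paired from general knowledge; list counts use all pairs. Per list, the median log2 change was set against 10000 random lists of the same size drawn from 20 classes of mean expression, with Benjamini-Hochberg adjustment over lists. Named genes followed a rule fixed beforehand. It took OsDDM1a, OsDDM1b and OsDRM2. It took the 10 largest rises and falls at a mean count of at least 20, printed as 2 identifiers each because they could not be named. Per list it took up to 4 members with the smallest adjusted p, or the 2 with the highest level where none passed. It also took the 3 peaks per mark with the highest fold and the 3 windows of 10 kb with the largest fall and rise. The limit to accepted names was not part of this rule. Members that met the rule without an accepted name were therefore left out, and members with a larger adjusted p were named in their place. OsFIE1 had the smallest adjusted p of its list, but the exception for its name was not part of the rule either.

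Overlaps were counted from 1 bp on. Peaks were placed at random on their own chromosomes 1000 times, taking the largest coordinate in the files as chromosome length. Positions shared between the small RNA lists were set against 1000 rotations along each chromosome. Intervals of shares are Wilson 95% intervals and cover counting error only, since amplified reads are not independent molecules. Reads per 1000000 refer to the listed 24-nt reads. Whole reads per library were recovered for the loci with the lowest mean counts from the steps that 1 read makes in the mean, within 2e-08.

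The calculations on lists, peak placement, recovered reads and order along the chromosomes were tested on simulated data, and the others were not. Lists of 5 genes shifted by 1.5 on the log2 scale were found in 100% of cases and unshifted lists called in 0%, over 29212 genes. In that simulation fold changes were shuffled over genes. It therefore does not cover smaller shifts, members that change together, or a link between change and expression. Planted peak overlaps came out 4.20 times above random and independent ones at 0.951. Recovered reads were right in 100% of 5000 simulated genes, and a planted relation along the chromosomes was found in 100% of 20 profiles, against 5% of even ones, over 55801 loci. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

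Alternatives were another p limit, a fold limit, filters on mean count, stronger peaks, other overlaps, positions in place of reads, other windows and minimums; those added after seeing the data are named in the closing section. 5 planned results were left out because no gene positions or descriptions for these locus identifiers were used here: the shares of changed genes with either mark or near small RNAs, small RNAs in and near genes, and transposable element genes among changed genes.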

Results

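Leaves of 12-day-old rice seedlings (Oryza sativa, japonica) were profiled in 17 samples, and the processed files used here covered 8 of them. They held a gene expression comparison of the osddm1a/1b mutant with its wild type Cr-DJ-1 (2 RNA-seq libraries each), lists of 24-nt small RNA alignments from osdrm2 and from Cr-DJ (1 library each), and peak lists for H3K27me3 in Cr-DJ and H3K9me2 in ZH11 (1 library each). DDM1 is a chromatin remodeller needed for DNA methylation of heterochromatin, and DRM2 is the methyltransferase that is guided by 24-nt small RNAs. H3K27me3 is the histone mark of Polycomb repression and H3K9me2 a mark of silent heterochromatin. Cr-DJ is material of the variety DongJin, the background of the mutants, whereas ZH11 is another variety. The bisulfite libraries, the osdrm2 RNA-seq libraries and their own wild type were not analysed here.

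The first comparison asked which genes changed in osddm1a/1b. OsDDM1b, one of the paired rice copies of DDM1, fell by 3.27 on the log2 scale in the mutant (SE 0.16, adjusted p = 1.27e-86) in the authors' deposited table, where wild type stood 9.67-fold above the mutant. The table does not state the direction of its fold changes. Mutant over wild type is the likely reading once the deposited sign is turned, because the series' file list names the wild type first and OsDDM1b is then the lowered gene. That choice rests partly on OsDDM1b, so OsDDM1b is no independent check of the labels, and every "higher" and "lower" below carries the same condition. OsDDM1a, the other copy, stood at -0.14 in the authors' deposited table (SE 0.16, adjusted p = 0.511) and OsDRM2 at 0.07 (SE 0.08, adjusted p = 0.512), and neither passed the test. The labels of the mutant libraries name osddm1a/1b in their titles but osddm1b alone among their characteristics, and that conflict stayed open.

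Of 29212 loci with an adjusted p in the authors' deposited table, 13641 (46.7%) passed 0.05, and 8048 of these were higher and 5593 lower in the mutant. The surplus of rises lay in loci with low counts. In the authors' deposited table, 2092 loci rose and 549 fell at a mean count of 10 to 100, and 809 rose and 44 fell at 4.55 to 10, whereas 2836 rose and 2714 fell at 100 to 1000 and 2130 rose and 2275 fell at 1000 or more. The large changes were mostly rises. In the authors' deposited table, 3407 loci were at least 2-fold higher and 856 at least 2-fold lower, so that 79.9% of changes of this size were rises against 59.0% of all changes. At 8-fold or more the authors' deposited table had 847 rises and 44 falls, and at 32-fold or more 265 rises and 7 falls. The largest rises among loci with a mean normalized count of at least 20 were LOC_Os07g49350 (log2 8.93, SE 0.27) and LOC_Os02g37230 (8.75, SE 0.26) in the authors' deposited table, and the 10 largest rises all lay at 7.81 or above. LOC_Os03g45619 fell by 6.72 (SE 0.12) and LOC_Os09g19229 fell by 6.54 (SE 0.27) in the authors' deposited table, and the 10 largest falls all lay at -4.77 or below. Changes of low genes are moderated towards 0 in these values. Both genotypes had 2 libraries that the labels call repeats, with no word on separate plants. The p-values therefore rest on the model's estimate of the spread between these libraries, which may be technical.

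Among genes of DNA methylation and chromatin remodelling, the only fall was that of OsDDM1b, which had helped to set the direction. Of 13 fixed members, 5 rose, OsDDM1b fell and 7 did not pass the test in the authors' deposited table. The maintenance methyltransferase genes OsMET1b (log2 1.29, SE 0.17, adjusted p = 7.02e-14) and OsCMT3a (1.23, SE 0.12, adjusted p = 5.02e-24) rose in the authors' deposited table, as did OsCMT3b (0.86, adjusted p = 0.0293) and the DNA glycosylase gene ROS1c (0.39, adjusted p = 0.000383). Of 13 genes of RNA-directed DNA methylation and small RNA pathways, 2 rose, 1 fell and 10 did not pass in the authors' deposited table. The Argonaute genes OsAGO18 (0.88, SE 0.12) and OsAGO4b (0.16, SE 0.05) were the members that rose in the authors' deposited table. Among 6 Polycomb genes, 2 rose, 2 fell and 2 did not pass in the authors' deposited table. OsFIE1, a Polycomb gene whose expression is normally restricted to the endosperm, rose by 5.15 on the log2 scale (SE 0.33, adjusted p = 2.67e-54), a 35.5-fold change in the authors' deposited table, whereas OsEZ1 fell by 0.21 (SE 0.09, adjusted p = 0.0381). The medians of these 3 lists (0.11, -0.03 and -0.05) lay at the percentiles 73.4, 47.6 and 43.0 of 10000 random lists matched on mean expression, inside the central 95%. For the Polycomb list the mean, drawn up by OsFIE1, was 0.80 and so differed in sign from the median.

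Light harvesting genes rose. Of 17 members of the photosynthesis list, 13 rose and 4 fell in the authors' deposited table, and the list median of 1.21 lay above all 10000 matched random lists. The light-harvesting genes CAB2R (1.62, SE 0.05), CAB1R (1.23, SE 0.07) and Lhcb2a (1.21, SE 0.07) rose in the authors' deposited table, while RbcS3, which encodes a small subunit of Rubisco, fell by 0.17 (SE 0.01). All 9 genes of cell division and DNA replication rose in the authors' deposited table, with a median of 0.96 at the percentile 99.98. Among them were the mitotic kinase gene CDKB2 (1.14, SE 0.11), the B-type cyclin gene CYCB2;2 (1.16, SE 0.14), the replication clamp gene PCNA (0.90, SE 0.09) and the replicative helicase gene MCM5 (1.01, SE 0.11), all in the authors' deposited table. The names of the other members that fell in the photosynthesis list could not be checked. The 3 KNOX genes of the shoot meristem, a cell type outside the mature leaf, rose alongside these groups. OSH1 stood at 1.59 (SE 0.36), OSH15 at 1.21 (SE 0.38) and OSH71 at 2.0 (SE 0.33) in the authors' deposited table, and their median lay at the percentile 88.2 (adjusted p = 0.442).

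Several regulators of flowers rose and flowering time genes fell. Of 16 tested flower and inflorescence regulators, 7 rose, 1 fell and 8 did not pass in the authors' deposited table, with a median of 0.71 at the percentile 98.2 (adjusted p = 0.0905), and the KNOX genes rose with them. The floral organ genes OsMADS16 (1.80, SE 0.21), OsMADS17 (2.24, SE 0.27) and OsMADS4 (2.1, SE 0.31) and the gene OsMADS18 (0.81, SE 0.18) rose in the authors' deposited table. OsMADS3, the member that fell, stood at -1.07 (SE 0.37) in the authors' deposited table and is named after its value was seen. All 5 tested flowering time genes fell in the authors' deposited table, with a median of -0.88 at the percentile 0.03. OsMADS50, a promoter of flowering, fell by 2.43 (SE 0.16), OsMADS56 fell by 1.84 (SE 0.10) and Hd1, the rice relative of CONSTANS, fell by 0.70 (SE 0.18) in the authors' deposited table.

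Stress-related genes split. Among 9 tested genes of dehydration, abscisic acid and salt, 5 rose and 3 fell in the authors' deposited table, with a median of 0.53 at the percentile 96.6 (adjusted p = 0.144). DREB1B (2.98, SE 0.14) and DREB1A (1.30, SE 0.11), which encode cold-response transcription factors, the lectin gene SalT (2.36, SE 0.06) and OsbZIP23 (0.53, SE 0.06) rose in the authors' deposited table. The 3 falls, named after their values were seen, were those of the dehydrin genes RAB16A (fell by 2.36, SE 0.31) and RAB16B (fell by 1.03, SE 0.38) and of OsLEA3 (fell by 0.87, SE 0.38) in the authors' deposited table. Of 11 genes of phytoalexin synthesis, 1 rose and 4 fell in the authors' deposited table, with a median of -0.26 at the percentile 1.2 (adjusted p = 0.072). Against random lists the median was -0.36 at a mean count of at least 10 (adjusted p = 0.0455). With matched names alone, chosen after seeing the data, it was -1.39 (adjusted p = 0.0006, from a raw p of 0 that was set to 1 in 10000). The call thus depends on the members counted. CYP71Z7 fell by 2.17 (SE 0.36), OsCPS2 fell by 2.07 (SE 0.36), OsKSL7 fell by 1.56 (SE 0.31) and OsCPS4 fell by 1.23 (SE 0.25) in the authors' deposited table. Of 12 defence genes, 4 rose and 4 fell in the authors' deposited table. The largest fall and the largest rise among them were in members whose names could not be checked. These were LOC_Os01g28450 (fell by 4.19, SE 0.31) and LOC_Os06g44010 (2.87, SE 0.18) in the authors' deposited table. WRKY71 (1.4, SE 0.04) and WRKY76 (1.14, SE 0.13) rose there, while NH1, the rice relative of the immune regulator NPR1, fell by 0.75 (SE 0.07) and WRKY62 fell by 0.65 (SE 0.18), again in the authors' deposited table. Of 12 heat shock genes, 1 rose, 3 fell and 8 did not pass in the authors' deposited table, with a median of -0.30 at the percentile 0.33. The small heat shock protein gene LOC_Os03g16020 (fell by 1.4, SE 0.37) and the heat stress factor genes HsfA2a (fell by 0.95, SE 0.34) and HsfA2c (fell by 0.39, SE 0.16) were the falls in the authors' deposited table, and the small heat shock protein gene LOC_Os03g16040 rose (0.52, SE 0.20).

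Markers of other tissues and reference genes completed the fixed lists. None of 3 tested root genes passed in the authors' deposited table, where OsLsi1 stood at 0.01 (SE 0.12) and OsIRT1 at -0.16 (SE 0.38). Of 5 tested seed storage and endosperm genes, 2 fell in the authors' deposited table, among them GluA2 (fell by 0.40, SE 0.17, adjusted p = 0.0481). Of 4 reference genes, ACT1 rose (0.69, SE 0.04) and the other 3 did not pass in the authors' deposited table. The list medians lay at the percentiles 31.6, 25.3 and 60.0, and that of the defence list at 39.2. With Benjamini-Hochberg adjustment over the 15 lists, 4 list medians stood apart from random lists. They were those of photosynthesis (adjusted p = 0.0015), cell division (0.003), flowering time (0.003) and heat shock (0.0248). For photosynthesis no random list reached the median. Its raw p of 0 was set to 1 in 10000 before adjustment, so its adjusted p depends on that setting. Heat shock lost its call among genes with a mean count of at least 10 (adjusted p = 0.198). The random lists drew genes independently, whereas members of a list can change together, so these p-values can be too small. They do not measure spread between plants. Adjusted over the list alone, 14 lists had the same counts of rises and falls. In the seed storage list 1 gene in place of 2 fell, because GluA2 no longer passed (adjusted p = 0.0557).

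**Figure D1:**
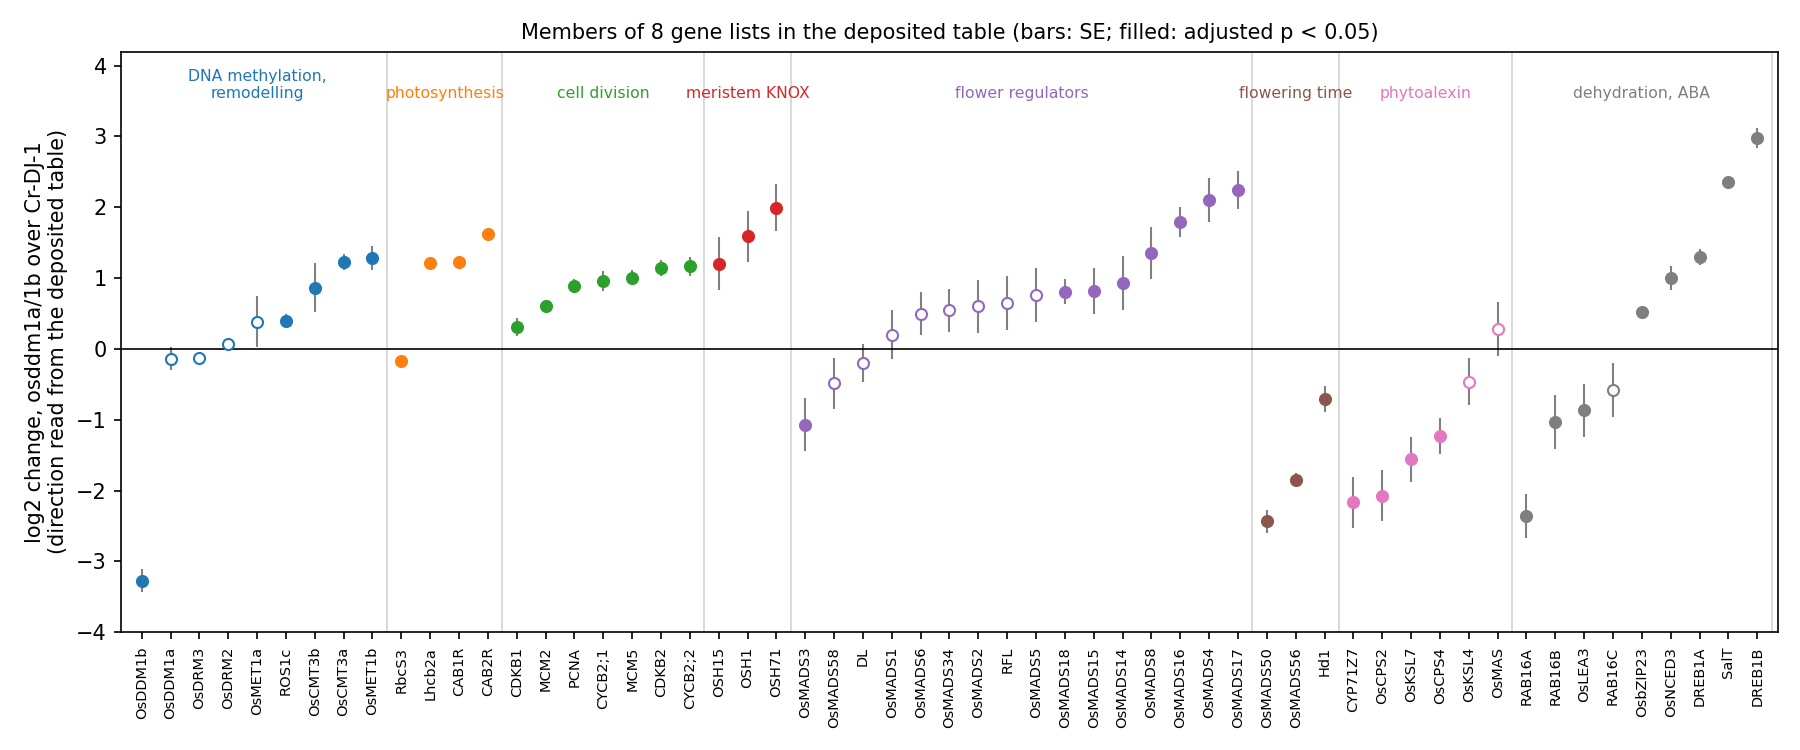
The vertical axis shows the log2 change of each gene, osddm1a/1b over Cr-DJ-1, from the authors' deposited table, with its standard error, for the members of 8 fixed lists whose names were matched, plus OsDDM1a and OsDDM1b; filled points passed an adjusted p of 0.05. OsDDM1b lies lowest at -3.27, the cell division and KNOX genes lie above 0 and the flowering time genes below 0.

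The second comparison set the histone marks against each other, each called from 1 library without a control, so that there was no replicate check. H3K27me3 in Cr-DJ had 13385 peaks over 28.1 Mb, with a median length of 1541 bp and a median fold enrichment of 4.01. H3K9me2 in ZH11 had 10159 peaks over 29.3 Mb, with a median length of 2466 bp and a median fold of 3.20. Folds are the authors' own values per peak. Peaks held 27.7% of 19709518 reads for H3K27me3 and 21.9% of 19160896 reads for H3K9me2. H3K9me2 covered between 6.08% of chromosome 3 and 8.79% of chromosome 7. The H3K27me3 peaks with the highest fold were on chromosome 2 from 1 to 624 (17.15-fold), on the unanchored sequence Sy from 380391 to 381231 (15.11-fold) and on chromosome 10 from 911 to 1542 (14.97-fold). For H3K9me2 they were on chromosome 2 from 1 to 1464 (22.83-fold), on chromosome 6 from 14672252 to 14673079 (11.58-fold) and on chromosome 1 from 906 to 2397 (10.89-fold). The highest peak of H3K27me3 thus lay inside that of H3K9me2 at the start of chromosome 2. Without a control, enrichment there could not be checked. The genome build was not given in the sources used here, and no gene annotation for it was used.

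The marks mostly avoided each other. Of the H3K27me3 peaks, 405 of 13385 (3.03%, Wilson 95% interval 2.75 to 3.33%) met an H3K9me2 peak by at least 1 bp. Random placement of the H3K27me3 peaks on their own chromosomes gave 12.9% (12.4 to 13.5% in the central 95% of 1000 placements), 4.27 times as many, and no placement was as low as the observed count. In the other direction 383 of 10159 H3K9me2 peaks (3.77%) met an H3K27me3 peak, against 16.7% at random. Across 371 bins of 1 Mb the cover by both marks was inversely related (Spearman -0.29), although bins are not independent replicates. The marks come from different varieties. Random placement also reaches sequence in which no read can be placed, which lowers the random overlap.

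The third comparison asked how 24-nt small RNAs differed in osdrm2. The list of Cr-DJ held 106418 alignments at 11243 positions and that of osdrm2 155764 at 20576 positions. Each genotype had 1 library, so there was no test, and intervals cover counting error only. Every listed position had at least 4 reads, so a position at 0 is only unlisted, and the list totals are not the depth of the libraries. The ratio of osdrm2 to Cr-DJ was 1.46 for reads and 1.83 for positions, but 1.10 for reads at positions with at least 10 reads. For positions it reversed to 0.939 after osdrm2 was thinned to the Cr-DJ total and was 1.06 and 1.23 under other thinnings, so no direction is read from the number of positions. The median was 5 reads per listed position in both lists, and 2270 positions had at least 10 reads in Cr-DJ against 2574 in osdrm2. In both lists the most abundant position lay on chromosome 2 from 1553207 to 1553230, with 6379 reads (5.99%) in Cr-DJ and 6871 (4.41%) in osdrm2.

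Of the Cr-DJ positions, 27.8% (Wilson 95% interval 27 to 28.6%) were overlapped by a listed osdrm2 position, and 17.1% of osdrm2 positions by one of Cr-DJ. Lists rotated along their chromosomes gave 0.234% and 0.12%. Among 116 windows of 10 kb with at least 100 reads in either list, 58 were higher and 58 lower per 1000000 listed reads in osdrm2, 102 were present in both lists, 12 only in that of Cr-DJ and 2 only in that of osdrm2. The largest falls were on chromosome 2 from 1550001 to 1560000 (61616 per 1000000 in Cr-DJ and 45428 in osdrm2, while the reads themselves were more in osdrm2, 7076 against 6557), on chromosome 1 from 37780001 to 37790000 (12131 per 1000000, from 1291 reads, in Cr-DJ and listed at 0 in osdrm2) and on chromosome 12 from 9350001 to 9360000 (8250 and 2825). The largest rises were on chromosome 8 from 9070001 to 9080000 (2255 and 5322), on chromosome 8 from 8700001 to 8710000 (207 and 2176) and on chromosome 10 from 4830001 to 4840000 (9397 and 11113).

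The small RNAs of the libraries differed in where they lay relative to the marks. In Cr-DJ, 1.93% of 24-nt reads and 1.76% of positions (198 of 11243, Wilson 95% interval 1.53 to 2.02%) lay in H3K9me2 peaks, below the random range for positions of 7.0 to 8.73%. In osdrm2, 5.23% of reads and 6.11% of positions (1258 of 20576, 5.79 to 6.45%) did so, also below its random range of 7.32 to 8.52%. How reads with several positions were treated is not given, so a share below the range may come from mapping alone. Random placement also reaches sequence in which no read can be placed. That lowers the random shares, so it can help to put a share above the range but not below it. At positions with at least 10 reads the shares of reads lay closer together, at 2.13% in Cr-DJ and 3.82% in osdrm2. H3K27me3 peaks held 11% of Cr-DJ positions (1242 of 11243, 10.5 to 11.6%), above the random range of 6.85 to 8.41%. They held 6.93% of osdrm2 positions (1426 of 20576, 6.59 to 7.29%), just below the range of 7.02 to 8.11%. How far the lowered random shares account for the Cr-DJ share above the range was not tested. By reads, the shares in H3K27me3 peaks were 9.17% in Cr-DJ and 6.25% in osdrm2, both inside the random ranges of 5.81 to 13.6% and 6.20 to 11.9%. Across bins of 1 Mb, H3K9me2 cover was inversely related to the density of Cr-DJ positions (Spearman -0.54) and hardly related to that of osdrm2 (0.06). The 93 bins with most H3K9me2 had a median of 19 positions per Mb in Cr-DJ and 56 in osdrm2, against 39.5 and 52 in the 92 bins with least.

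**Figure D2:**
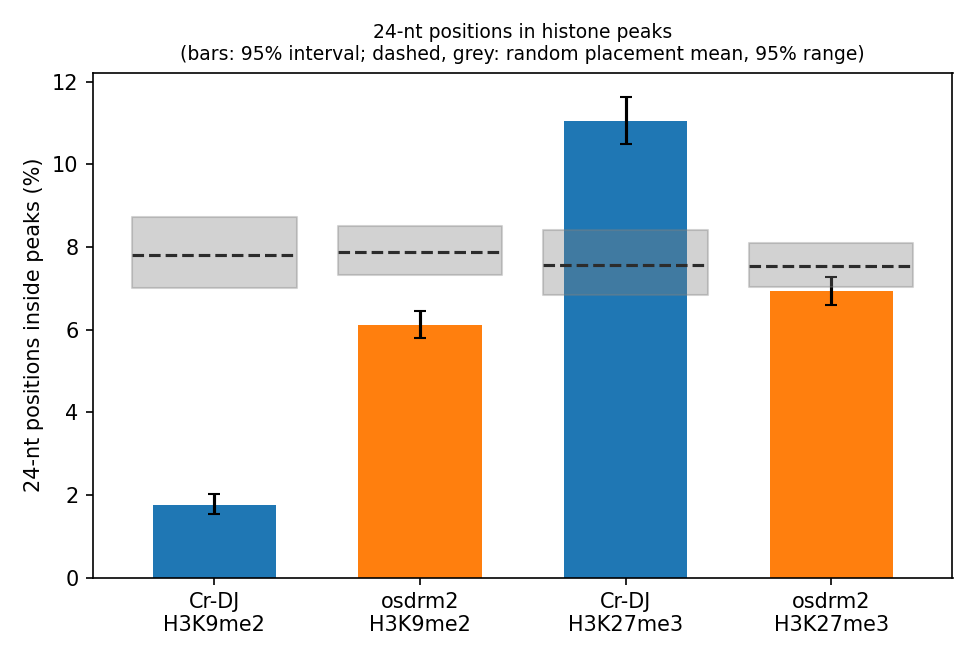
Bars give the percent of listed 24-nt positions inside H3K9me2 (ZH11) and H3K27me3 (Cr-DJ) peaks for 1 library of Cr-DJ (blue) and 1 of osdrm2 (orange), with Wilson 95% intervals; dashed lines and grey bands give the mean and the central 95% of 1000 random placements of the peaks. The share in H3K9me2 peaks was 1.76% in Cr-DJ and 6.11% in osdrm2, and in H3K27me3 peaks 11% and 6.93%.

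**Figure D3:**
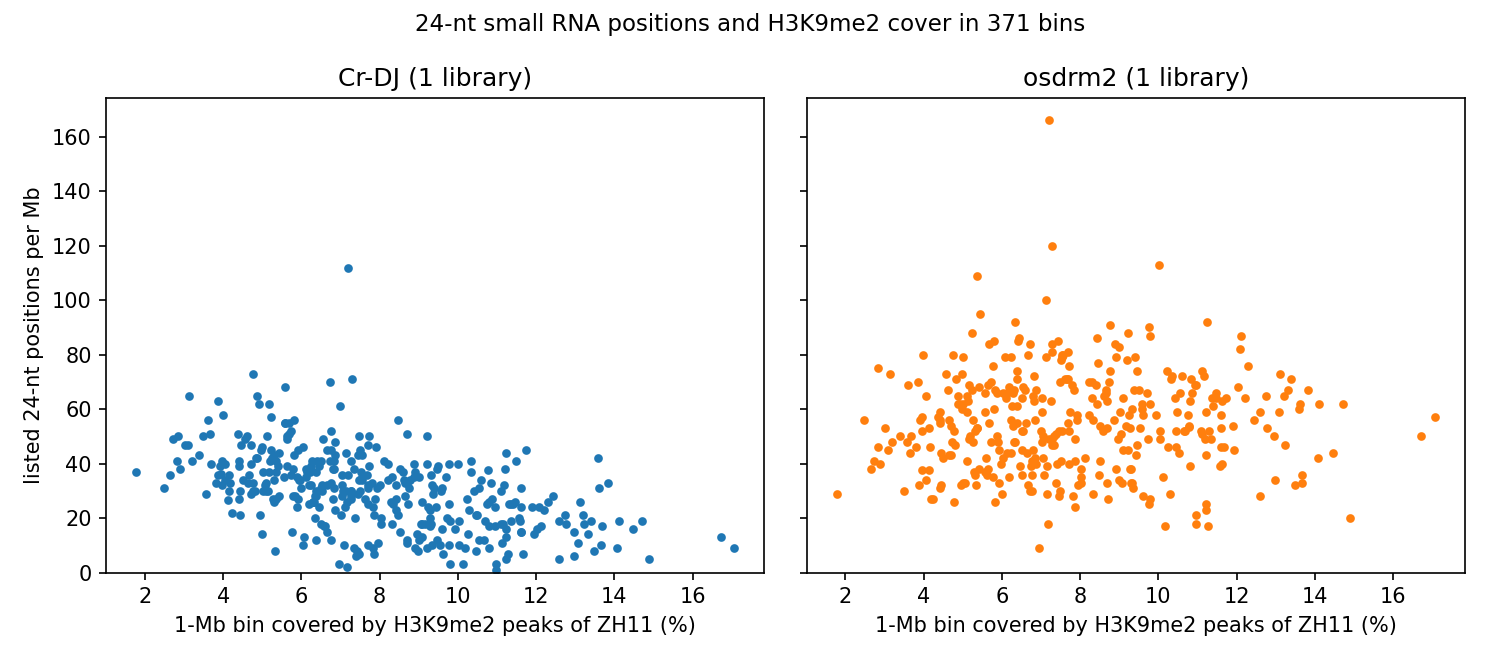
Each point is 1 of 371 bins of 1 Mb, with the percent of the bin covered by H3K9me2 peaks of ZH11 on the horizontal axis and the listed 24-nt positions per Mb on the vertical axis, for Cr-DJ (left) and osdrm2 (right). Density falls with H3K9me2 cover in Cr-DJ (Spearman -0.54) and not in osdrm2 (0.06).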

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

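Rotation, covered bases, H3K9me2 peaks counted, matched names, identical positions, at least 10 reads per position, the list without its most abundant position, positions of 1 library only and thinning were chosen after seeing the data. The count of changed genes stayed within 1.5 times of 13641 at an adjusted p of 0.01 (10901), without a filter on low counts (12897) and at a mean count of at least 10 (12723), and was 4263 (3407 higher, 856 lower) at 2-fold or more, which the stricter limit itself causes. The number of lists apart from random lists was 4 at a mean count of at least 10 and 5 with matched names; heat shock lost its call at that mean (median -0.25) and phytoalexin synthesis gained one there (-0.36) and with matched names (-1.39). The marks overlapped 3.44 to 5.62 times less than random under every alternative run. The osdrm2 to Cr-DJ ratio of 24-nt amounts was 1.83 by positions, 1.10 at positions with at least 10 reads, and reversed to 0.939 for positions after thinning osdrm2 to the Cr-DJ total, which left only 81901 reads above the floor of 4. For positions it was 1.23 when thinned until the reads above the floor matched Cr-DJ, and 1.06 when thinned by the median ratio of abundant shared positions, so the size and the direction for positions depend on how depth is matched. Of 10-kb windows with at least 10 reads 62.1% were higher in osdrm2, against 50% at 100 reads. For 1-kb windows these shares were 58.5% at 10 reads and 45.9% at 100 reads. The share of Cr-DJ found in osdrm2 was 37.9% by reads, 23.2% for identical positions, 35.6% at positions with at least 10 reads, and, for windows, 82.4% (10 kb, 100 reads), 60.4% (10 kb, 10 reads), 73.5% (1 kb, 100 reads) and 38.5% (1 kb, 10 reads); the cause was not tested. Of 52 alternative values behind the main comparisons 30 stayed the same, 12 moved, 9 newly passed a random range and 1 reversed, and of 29 others 25 stayed the same, 1 moved, 2 newly passed and 1 no longer passed. The shares in H3K9me2 peaks stayed below random under every alternative run. The Cr-DJ share in H3K27me3 peaks passed above the random range by positions (11%, also with rotation), without the most abundant position (9.75%) and for its own positions (12.1%), and at 10 reads it was 7.46%. The osdrm2 share passed below the range by positions (6.93%, also with rotation), in the stronger peaks (3.57%), with rotation (6.25%) and for its own positions (6.83%); the cause was not tested. No paired analysis was possible because the authors' deposited table has no value per library. For the same reason the refits, other scalings, block, left-out libraries and estimated correlation were not run; limits on multiple mapping and scaling by another total were not run because the lists give neither, nor windows for shares in peaks, which are counted by base. With 1 library per mark and per small RNA genotype, depth limits what an unlisted position can show.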

Other observations

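Of the tests below, that on the share of reads in the 10% of loci with most, the thinning until reads above the floor matched, the higher floor and the reading of the limit on silent loci were chosen after results were seen. Loci at the edge of detection were read far more often in the mutant. For all 13646 loci with a mean count above 0 and below 4.55, the mean in the authors' deposited table resolved into whole reads of 4 libraries, 2 on each side of the comparison. The mutant libraries held 22483 and 23210 reads per unit of size factor in these loci and the wild-type libraries 8611 and 8472, a ratio of 2.68. In 3309 loci reads came from both mutant libraries and from neither wild-type library, against 327 loci with the opposite pattern. Of the 2157 low loci with at least 10 reads, 764 had all of them in the mutant and 33 all in the wild type. Which side is the mutant rests on the direction read from the table. The size factors set well-expressed loci near 0, so the excess is relative to those loci.

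An even background of stray reads, for example from genomic DNA, may add to the low loci. Below a mean count of 4.55, 22065 loci had no wild-type read. Loci at higher means were not resolved into reads, so any without a wild-type read there are left out, also over the segments below. Of the mutant reads in the 22065 loci, 68.3% lay in the 10% of loci with most, whereas the longest 10% of genes hold 31.4% of gene length in the reference table. The 10% of loci with most reads were picked by the reads themselves, at a mean of 1.25 mutant reads per locus. Of the 22065 loci, 66.1% had no mutant read. Counting noise alone therefore raises the share of the loci with most. The gene lengths also belong to another annotation, so background cannot be told apart from transcription here. Loss of silencing in the mutant remains open as a hypothesis.

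Each chromosome was split into 10 segments, 120 in all. Loci were split by the order of locus numbers and mark cover by equal parts of chromosome length, so loci and cover match only roughly. Only loci with a mean count below 4.55 could be called read in 1 genotype alone. The share of loci read only in the mutant correlated with H3K9me2 cover at Spearman 0.81, against at most 0.40 in the central 95% of 1000 rotated profiles. Means were 8.88% in the 30 segments with most H3K9me2 cover and 3.40% in the 30 with least. Loci read only in the wild type, which were far fewer, also followed it (0.39, rotated bound 0.24; means 0.836% and 0.354%), as did loci without a wild-type read (0.84), so a candidate explanation is that more silent loci lie there. Among loci without a wild-type read the correlation was 0.22, just above the rotated bound of 0.21 (12 of 1000 rotations as high; 15.9% against 14.1% in the same segments), which by the limit set beforehand would exclude the density of silent loci. That limit was judged too low only after this result was seen, because the relation had shrunk from 0.81, so release in H3K9me2-rich regions and the density of silent loci cannot be told apart here. With H3K27me3 cover the relation was inverse, at -0.53 for loci read only in the mutant (lower rotated bound -0.30) and -0.30 among loci without a wild-type read (-0.22). The covers of the marks were themselves inversely related (Spearman -0.29 across bins of 1 Mb), so their relations to these loci cannot be separated here.

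The larger share of osdrm2 positions in H3K9me2 peaks (3.47 times that of Cr-DJ) stayed when the totals of the lists were matched, with the same floor of 4 reads. After thinning osdrm2 to the Cr-DJ total, 20 draws gave 5.49 to 6.11%. When thinned until the reads above the floor matched, they gave 5.75 to 6.23%. All lay above the upper bound of 2.02% for Cr-DJ. The depth of the libraries is unknown, so a gap in depth larger than that of the lists was not covered. A floor of 10 reads shrank the difference to 2.34 times by positions (4.74%, Wilson 95% interval 3.98 to 5.63%, against 2.03%, 1.52 to 2.69%), and by reads it was 3.82% against 2.13%. A few regions do not carry the difference, since without the 20 bins of 1 Mb that added most the ratio was 6.07 (5.18% against 0.854%). Differences in library preparation, plant material or size selection between the single libraries may produce it as well as the loss of DRM2, and 1 library per genotype leaves these untested.

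For loci with a mean count between 100 and 1000 the standard errors of the authors' deposited table correspond to a median coefficient of variation of 8.4% beyond counting. It was 3.9% for the 6538 loci at 1000 to 10000 and 1.65% for the 221 at 10000 or more. Whether the libraries share plants or RNA stays open.

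Over the 120 segments of the chromosomes, loci at least 2-fold higher in the mutant correlated with H3K9me2 at 0.33 (rotated bound 0.19). The difference was small, with means of 6.46% in the 30 segments with most H3K9me2 cover and 5.53% in the 30 with least. Loci without a wild-type read also followed H3K9me2 cover (0.84). Whether the relation of the higher loci is separate from the density of such loci was not tested. Loci at least 2-fold lower stood at -0.12, inside the rotated range of -0.18 to 0.11. With H3K27me3 the loci at least 2-fold higher correlated inversely, at -0.21 (lower rotated bound -0.17). Means were 5.95% in the 30 segments with most H3K27me3 cover and 6.69% in the 30 with least.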
